A study of Drosophila melanogaster with 24 samples.

How the data were processed

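The 24 arrays measured total RNA of whole adult Drosophila melanogaster as biotin-labelled cRNA on Affymetrix expression arrays, per the labels. Per the submitters' processing notes, the authors used RMA, which corrects background, quantile-normalizes arrays and summarises the probes of a probe set; its version, any later scaling and whether all arrays were processed together are not given in the sources used here. The deposited values are intensities on a linear scale, from 5.2 to 20754, where log2 values had been assumed when the tests were chosen, so log2 was taken with no pseudocount. The column medians were 53.5 to 66.3 and the means 288 to 308, so the scale of the arrays was close but not identical, and no further normalization was applied. RMA on short probes compresses large differences, and a probe set at the low end of the scale may carry mostly background. The lower quartile of an array was 20.8 or more, and where a compared group of a named gene lay below that of every array, this is said beside its value.

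The table held 18952 probe sets. The 183 control probe sets were left out of the tests, and 0 of them passed limma when tested in the 6 comparisons of knockdown or over-expression with its control. Of the 18769 tested, 13647 name 1 gene (11982 distinct genes), 402 name several and 4720 are unnamed here; names came from the platform annotation, 13544 of them were matched to the Release 6 gene table, and 0 symbols changed. No gene was named from a probe set listing several. Coordinates are not printed because the array annotation names no assembly.

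Groups follow the labels: 4 genotypes in 2 sexes, 3 arrays each. Within a group arrays correlated at 0.974 to 0.992, no pair of arrays shared more than 24 equal values, and the median SD of a probe set within a group was 0.138 to 0.192 on the log2 scale. The first principal component held 89.0% of the variance over all arrays, and 46.6% among females and 29.4% among males.

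Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 24 arrays with 1 mean per group, leaving 16 residual degrees of freedom and a prior of 5.19. Each comparison was a contrast of group means, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05, two-sided. The contrasts were each manipulation against its own control in each sex and in the mean of both sexes, the difference of each effect between sexes, over-expression minus knockdown, the control genotypes against each other, and females against males among controls. Overlaps of calls were tested with two-sided Fisher exact tests. These treat probe sets as independent, and the compared calls share 1 estimate of each probe set's spread, so their p-values are a guide only. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

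The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Hr96; the 12 largest rises and 12 largest falls in each mean of both sexes among called probe sets that name 1 gene and move the same way in all 6 same-batch pairs; the 6 and 6 in each sex over its 3 pairs; the 5 largest in the effect differences; up to 4 called members of each list; and w, Yp1, Acp26Aa and Mst84Da as checks of the labels.

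The 27 gene lists were nuclear receptors, lipases, sterol and lipid transport, fatty acid and triglyceride synthesis, fatty acid oxidation, cytochrome P450s, glutathione S-transferases, UDP-glycosyltransferases, alpha-esterase cluster, oxidative stress response, digestive proteases and carbohydrases, immune peptides and effectors, heat shock proteins, insulin and adipokinetic signalling, larval serum and fat body proteins, cuticle proteins, yolk, chorion and vitelline membrane proteins, ovary germline, testis, male accessory gland, muscle, photoreceptor, neuron, circadian clock, eye pigment and transgene marker, RNA interference and cytosolic ribosomal proteins. Each was tested with limma camera at its preset correlation of 0.01 over 11982 genes, 1 probe set per gene (highest mean), adjusted over the 27 lists within a comparison. The preset correlation gave 35 calls in 6 comparisons; 0 held with an estimated correlation, and fry gave 0. Lists were tested in the other contrasts after the data were seen.

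Replicate numbers mark diet batches, per the labels, so they pair the samples. Deviations from the group means of same-numbered arrays correlated at -0.07 to 0.57 over the 12 compared pairs (mean 0.25), and 9 of the 12 were over 0.1. The batch was not in the tests reported first; a fit with the batch as a block was an alternative. Other alternatives were the compared arrays alone, a minimum mean log2 value of 5, a median shift, quantile normalization over all arrays or within each sex, eBayes with trend and robust, array weights, a 2-fold threshold, 1 probe set per gene, and leaving out each array in turn.

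The steps were tested on simulated data with 50 changed probe sets of each size among 18769. For knockdown females 13, 39, 50 and 49 of 50 were recovered at log2 changes of 0.5, 1, 2 and 3, with 11 false calls; for over-expression males 11, 44, 49 and 50, with 10. For the mean of both sexes the numbers were 29, 47, 50 and 50 in the knockdown, with 11, and 30, 44, 50 and 50 in over-expression, with 8. A list of glutathione S-transferases shifted by 0.5 among 11982 genes was called, and 0 other lists were. The simulated noise was independent between genes, so it cannot show how often camera calls lists wrongly when genes are correlated.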

Results

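Transcript levels were measured in whole adult fruit flies carrying transgenes that target Hr96, the gene of the nuclear receptor DHR96, which is known for roles in the response to foreign compounds and in triglyceride and sterol metabolism. The 24 Affymetrix arrays formed 8 groups of 3: each of 4 genotypes in females and in males. An RNA interference transgene (line 3) was driven by arm-GAL4, and its control carried arm-GAL4 alone. An over-expression transgene (line 35) was driven by Act5C-GAL4, and its control carried Act5C-GAL4 alone. GAL4 is a yeast transcription factor that switches on transgenes behind a UAS sequence. Flies were 0 to 3 days old, and the replicate number marks 1 of 3 batches of diet. The median intensity of an array lay between 53.5 and 66.3, and 18769 probe sets were tested. The labels call the replicates biological, and p-values weigh a difference against the spread between replicates. That spread was estimated over all 24 arrays, not from the compared groups alone. With 3 arrays in a group, the number of arrays limits the precision.

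Hr96 itself was read first, because it is the gene the transgenes target. In arrays labelled knockdown its log2 intensity was 7.98 ± 0.15 (SD, n = 3) in females against 7.81 ± 0.21 in the arm-GAL4 control, and 6.50 ± 0.09 in males against 6.64 ± 0.28. The log2 change was 0.17 (SE 0.31, limma adjusted p = 0.989) in females and -0.14 (SE 0.31, adjusted p = 1.00) in males, and 0.01 (SE 0.22, adjusted p = 0.999) in the mean of both sexes. No fall of Hr96 was therefore detected in the arrays labelled knockdown, and directions given for that genotype refer to its label alone. With over-expression Hr96 rose 2.64-fold in females (log2 change 1.40, SE 0.31, limma adjusted p = 0.0333) and 4.25-fold in males (2.09, SE 0.31, adjusted p = 7.4e-04), and it was higher in 6 of 6 pairs of the same diet batch. Among over-expression males, replicate 2 read 7.61, below the 9.28 and 9.39 of the other arrays. In females the call was lost on leaving out any of 5 arrays: over-expression replicate 1 (adjusted p = 0.141) or 2 (0.172), or control replicate 1 (0.0629), 2 (0.0621) or 3 (0.152). Fitted on the compared arrays alone, the rise missed the threshold in females (adjusted p = 0.114) and in males (0.0910).

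**Figure D1:**
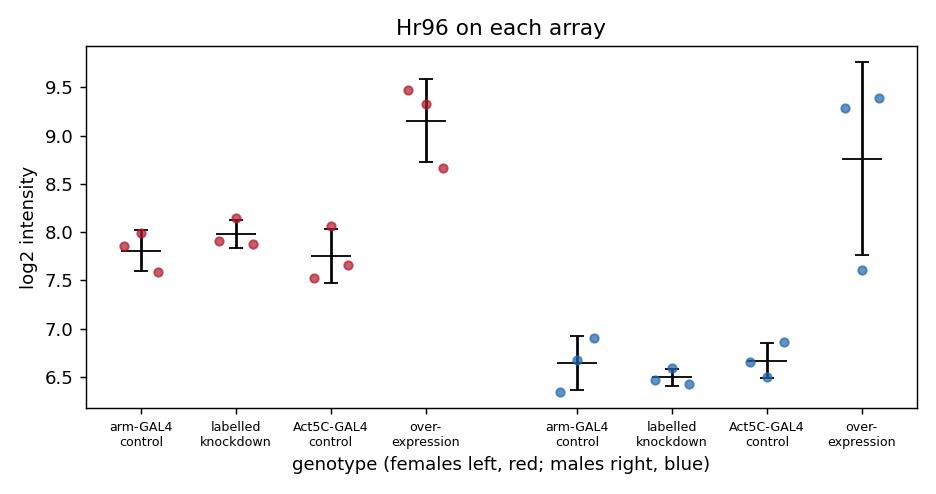
The log2 intensity of Hr96 (vertical axis) is plotted for each array (points) in the 8 groups (horizontal axis, females red and males blue), with the mean and SD of each group of 3 as a line and bars. Over-expression females average 9.15 and males 8.76, while arrays labelled knockdown average 7.98 and 6.50, beside 7.81 and 6.64 in their controls.

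The arrays labelled knockdown differed from the arm-GAL4 control in few genes. In the mean of both sexes CG13155 rose 2.58-fold (log2 change 1.37, SE 0.14, limma adjusted p = 2.9e-05, n = 6 arrays per genotype), Zip102B, a zinc transporter, rose 1.83-fold (SE 0.13 on the log2 scale), vari, a scaffold protein of septate junctions, rose 1.51-fold (SE 0.10), and CG18549 rose 1.45-fold (SE 0.08). All 4 were higher in 6 of 6 pairs of the same diet batch, which the rule for named genes required. The call of vari was lost without labelled females replicate 1 or 3, labelled males replicate 1 or 3, control females replicate 1 or control males replicate 2 (adjusted p = 0.0550 to 0.0822). In females CG1304, a gene on the X chromosome, rose from a log2 intensity of 3.83 to 7.01 (SE 0.25, adjusted p = 2.2e-07), and Cht10, a chitinase gene, rose by 1.27 (SE 0.14). In both, the control mean lay below the lower quartile of every array, where the size of a change is uncertain. CG1304 read 8.07 in females and 8.05 in males of the Act5C-GAL4 control, and 8.45 and 7.63 with over-expression. Its level thus also differed between control genotypes without an Hr96 transgene. In males CG13155 rose 3.01-fold (SE 0.20), CG15635 rose 2.75-fold (SE 0.15) and CG32006 rose 2.37-fold (SE 0.17).

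Limma called 4 probe sets in females labelled knockdown, all higher, 5 in males (4 higher, 1 lower) and 11 in the mean of both sexes (10 higher, 1 lower). Unadjusted p-values under 0.05 numbered 795, 410 and 621. Of the 11 calls in the mean, 5 moved the same way in all 6 same-batch pairs. The rest had the sign of the mean in only 3 or 4 of 6. Besides the genes above, unnamed probe sets were called: 1640377_s_at (log2 change 3.53) and 1624393_at (1.21) in females, and 1630934_at (4.16) and 1624819_s_at (-1.79) in males. These probe sets, and CG1304, Cht10 and CG15635 in the mean, were named after their values were seen, because the counts are small. 1640377_s_at read 8.70 in females labelled knockdown, against 5.17 in arm-GAL4 control females. Males of these genotypes read 4.82 and 4.91. Over-expression and Act5C-GAL4 control flies read 8.4 to 9.1 in both sexes, so its level also differed between control genotypes without an Hr96 transgene. With diet batch as a block the counts were 7 in females and 8 in males, and the mean gave 16 (10 higher, 6 lower), or 36 with array weights (20 higher, 16 lower). With arrays shifted to a common median, females gave 6 (5 higher, 1 lower). Leaving out control females replicate 1 or 3 gave 8 or 7 calls, and leaving out males labelled knockdown replicate 2 gave 8.

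In the arrays labelled knockdown 0 members of any gene list passed limma over all probe sets in females, males or the mean. In females the median log2 change was -0.18 for 83 cytochrome P450s, -0.25 for 25 immune peptides and effectors, -0.12 for 34 glutathione S-transferases, -0.20 for 35 digestive proteases and carbohydrases and -0.05 for 77 cuticle proteins, each lower by camera with its preset correlation. Every list call in females labelled knockdown, the yolk list included, was lost with an estimated correlation (adjusted p = 0.724 or more), and with diet batch as a block those of glutathione S-transferases (adjusted p = 0.0746) and cuticle proteins (0.0537) were lost as well. The 17 yolk, chorion and vitelline membrane proteins had a median of 0.68, and the diet batches gave 0.51, 1.68 and -0.12. Without control females replicate 2 the calls of yolk (median 0.09, adjusted p = 0.718), glutathione S-transferases (0.0915), digestive (0.367) and cuticle genes (0.0569) were lost, and without control females replicate 3 those of cytochrome P450s (0.0919), glutathione S-transferases (0.213), digestive (0.0919), immune (0.152) and cuticle genes (0.0766). Control females replicate 1 and labelled replicate 3 ended the cuticle call (0.227 and 0.335), labelled replicates 1 and 2 the glutathione S-transferase call (0.0869 and 0.0743), and labelled replicate 2 the digestive call (0.318). In males the neuron list fell (median -0.38, 13 genes, adjusted p = 1.1e-06), with batch values of -0.06, -0.76 and -0.37, and the call was lost with an estimated correlation (adjusted p = 0.367). Small rises in males were called for lipases (median 0.10), fatty acid and triglyceride synthesis (0.15), fatty acid oxidation (0.13), UDP-glycosyltransferases (0.08), the male accessory gland (0.15) and cuticle proteins (0.07), all lost with an estimated correlation (adjusted p = 0.334 or more). Without males labelled knockdown replicate 2 the calls of lipases (adjusted p = 0.277), UDP-glycosyltransferases (0.0842) and accessory gland (0.0680) were lost. Labelled replicate 3 ended those of fatty acid synthesis and oxidation (0.0588 for each), control males replicate 1 the same calls (0.0687 and 0.0609), and control males replicate 3 those of oxidation (0.0506), UDP-glycosyltransferases (0.325) and cuticle (median -0.02, 0.433).

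In the mean of both sexes camera called neuron (-0.17), yolk, chorion and vitelline membrane proteins (0.45), immune peptides and effectors (-0.12), male accessory gland (0.12) and cytochrome P450s (-0.07). With an estimated correlation every one of these calls of the mean was lost (adjusted p = 0.860 or more). Adjusted over the list alone, 1 lipase rose in males, 1 cytochrome P450 fell in the mean, and 0 members of the other lists passed. Left-out arrays ended each call of the mean: neuron without females labelled knockdown replicate 2 (0.0718), and yolk without control females replicate 2 (0.378). The P450 call ended without labelled females replicate 1 (0.0524) or 2 (0.229), labelled males replicate 1 (0.458), control males replicate 2 (0.192) or control females replicate 3 (0.769). The immune call ended without labelled females replicate 1 (0.0524), labelled males replicate 1 (0.0852), control males replicate 2 (0.192) or control females replicate 3 (0.373). The accessory gland call ended without control females replicate 1 (0.131) or 3 (0.101), control males replicate 2 (0.0921), labelled males replicate 2 (0.134) or labelled females replicate 2 (median -0.02, 0.989).

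Over-expression was accompanied by many more calls, in both directions. In the mean of both sexes e, the enzyme that joins beta-alanine to dopamine in cuticle tanning, rose 4.01-fold (log2 change 2.00, SE 0.37, limma adjusted p = 0.00443, n = 6 arrays per genotype), and Fbp1, a fat body protein of larvae, rose 3.05-fold (SE 0.32). CG17298 rose 4.91-fold (SE 0.48), dyw 4.08-fold (SE 0.38) and CG13155 3.51-fold (SE 0.14). Each SE rests on 1 spread per gene shared by all 8 groups, and some of these genes varied more with over-expression. The SD of CG17298 was 1.34 in over-expression females and 2.13 in males, against 0.18 and 0.75 in the control. For e it was 1.22 and 1.52, against 0.42 and 0.43, so their SEs may be too small. The cytochrome P450 Cyp4p2 rose by 1.93 on the log2 scale (SE 0.11). There the Act5C-GAL4 control stood apart, at 5.26 against 7.18 with over-expression and 7.17 in flies labelled knockdown. Obp57a, an odorant-binding protein gene, had a log2 change of -2.50 (SE 0.22, adjusted p = 4.9e-07), of uncertain size because over-expression males lay below the lower quartile of every array. Drsl4, of the drosomycin family of antifungal peptides, fell 3.75-fold (SE 0.32), Lectin-galC1, a galactose-binding lectin, 3.56-fold (SE 0.31), Cyp4d21 2.92-fold (SE 0.18), and path, an amino acid transporter, 2.55-fold (SE 0.13). The fall of Cyp4d21 came mostly from males (log2 change -2.76), with -0.33 in females (limma adjusted p = 0.546).

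**Figure D2:**
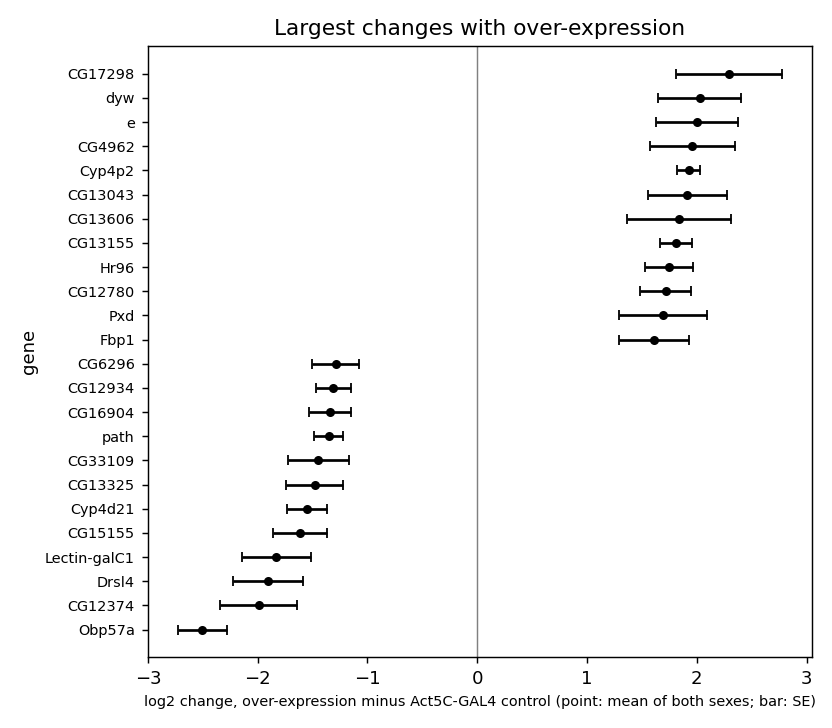
The log2 change from the Act5C-GAL4 control to over-expression (horizontal axis, mean of both sexes as points, SE as bars) is plotted for the 24 genes with the largest changes in each direction among those moving the same way in every same-batch pair (vertical axis). Values run from -2.50 for Obp57a to 2.30 for CG17298.

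Limma called 353 probe sets in the mean of both sexes, 175 higher and 178 lower, which name 303 distinct genes, and 83 of them differed by at least 2-fold. Other rises by the same rule were CG4962 (log2 change 1.96), CG13043 (1.91), CG13606 (1.84), CG12780 (1.72) and the peroxidase gene Pxd (1.69). The call of CG13606 held only without over-expression females replicate 3, over-expression males replicate 2, control females replicate 1 or control males replicate 1, and was lost without any other of the 12 arrays (adjusted p = 0.0596 to 0.144). That of Pxd held without these 4 or control females replicate 2 and was lost without any of the other 7 (0.0647 to 0.106). Other falls were CG12374 (-1.99), CG15155 (-1.61), CG13325 (-1.48), CG33109 (-1.45), CG16904 (-1.34), CG12934 (-1.31) and CG6296 (-1.29). With diet batch as a block the count was 595. It was 212 without control males replicate 3 and 565 without over-expression females replicate 3.

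In females the serine protease gene Ser12 rose 9.51-fold (log2 change 3.25, SE 0.23, limma adjusted p = 6.0e-08, n = 3 arrays per genotype). The rises of dyw (7.31-fold), CG4962 (5.72-fold), e (5.02-fold), CG13043 (4.91-fold) and obst-A, a chitin-binding protein of the cuticle (4.13-fold), had an SE between 0.38 and 0.55 on the log2 scale. The calls of CG4962 (adjusted p = 0.0848 to 0.202), e (0.0796 to 0.280), CG13043 (0.0673 to 0.180) and obst-A (0.0569 to 0.0867) were lost without over-expression females replicate 1 or 2 or control females replicate 2 or 3, and that of CG13043 also without control females replicate 1 (0.0522). The rise of e was 3.15-fold without over-expression females replicate 2, and that of dyw 11.0-fold without replicate 3. Falls were led by CG10154 (log2 change -2.16, SE 0.33), Obp57a (-2.02, SE 0.31), tut (-1.86, SE 0.21), CG6296 (-1.72, SE 0.30), CR44101 (-1.61, SE 0.17, with over-expression females below the lower quartile of every array, so of uncertain size) and CG15721 (-1.59, SE 0.35). Without over-expression females replicate 2 or control females replicate 3 the calls of dyw (adjusted p = 0.0880 and 0.0787), CG6296 (0.0645 and 0.0663) and CG15721 (0.189 and 0.211) were lost, the last also without control females replicate 2 (0.0593). Limma called 164 probe sets, 110 higher and 54 lower, or 383 with diet batch as a block. Single arrays moved this count widely: it was 75 without over-expression females replicate 1, 48 without replicate 2 and 723 without replicate 3, and 319, 53 and 36 without control females replicate 1, 2 and 3. Fitted on the 6 compared arrays alone it was 12.

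In males CG11598 fell 15.8-fold (log2 change -3.98, SE 0.20, limma adjusted p = 6.9e-11, n = 3 arrays per genotype), and Cyp4d21, a P450 of the male fat body, fell 6.78-fold (SE 0.26). CG42828 fell 6.32-fold (SE 0.25), Drsl4 6.11-fold (SE 0.45), CG12374 6.07-fold (SE 0.50), and Obp57a had a log2 change of -2.98 (SE 0.31). The fall of CG12374 was 10.7-fold without over-expression males replicate 3, and 3.91-fold without replicate 2, where the call was lost (adjusted p = 0.0568). CG43085 rose by 2.20 (SE 0.14), CG18233 by 1.85 (SE 0.17) and CG3528 by 1.70 (SE 0.17) on the log2 scale. For Obp57a, CG43085 and CG18233 the lower mean lay below the lower quartile of every array, where the size of a change is uncertain. CG31244 (log2 change 2.60, SE 0.25) and Cyp4p2 (1.83, SE 0.15) were also called higher, but the Act5C-GAL4 control stood apart: CG31244 read 6.70 there, against 9.30 with over-expression, 8.83 in males labelled knockdown and 8.86 in the arm-GAL4 control. Limma called 219 probe sets, 82 higher and 137 lower, or 358 with diet batch as a block. The count was 134 without over-expression males replicate 2, 90 without control males replicate 3 and 101 on the 6 compared arrays alone.

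In the mean of both sexes single genes of lipid metabolism and detoxification changed with over-expression, while camera called none of these lists. The fatty acid synthases FASN3 and FASN2 fell (log2 change -1.05, SE 0.16, and -1.03, SE 0.13), the only members of 20 in fatty acid and triglyceride synthesis to pass limma over all probe sets, and 3 fell when adjusted over the list alone. whd, the carnitine palmitoyltransferase of fatty acid oxidation, rose (0.66, SE 0.10) and Acox57D-p, a peroxisomal oxidase, fell (-0.44, SE 0.11), leaving 12 of 14 members that did not pass, and adjusted over the list alone the counts were also 1 and 1. Of 25 lipases 1 rose (CG7329, 0.51) and 3 fell (CG6296, -1.29, CG17097, -0.68, and CG2772, -0.67), or 3 and 6 adjusted over the list alone. CG7329 rose in males alone (1.02, against -2.8e-04 in females). Of 34 glutathione S-transferases GstS1 (0.80) and 1 other rose while GstE3 (-1.04), GstE5 (-0.93) and GstE7 (-0.81) fell, or 3 and 7 adjusted over the list alone. Of 83 cytochrome P450s 3 rose and 5 fell, among them Cyp6g1 (-1.12) and Cyp4e3 (0.90), or 4 and 9 adjusted over the list alone. Ugt36A1 rose (0.69) and Ugt35C1 fell (-1.17) among 35 UDP-glycosyltransferases, and Gclm (-0.45) and ref(2)P (-0.41) fell among 14 genes of the oxidative stress response, where 4 fell adjusted over the list alone. Several of these calls were lost without 1 of the 12 arrays. Acox57D-p (adjusted p = 0.0568 to 0.109), GstS1 (0.0562 to 0.139) and ref(2)P (0.0505 to 0.0924) each held only on leaving out 3: over-expression females replicate 3 for all, with control females replicates 1 and 3, control females and males replicate 1, or over-expression males replicate 3 and control males replicate 1, in that order. Cyp4e3 held only on leaving out over-expression females replicate 2, over-expression males replicate 1, or control females or males replicate 1 (lost at 0.0612 to 0.128). Gclm was lost without over-expression females replicate 2, over-expression males replicate 2 or control males replicate 2 (0.0518 to 0.0670), and GstE7 without control males replicate 2 (0.0521).

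In males the lists themselves shifted lower by camera: cytochrome P450s (median log2 change -0.14, 2 rose and 5 fell, or 3 and 12 adjusted over the list alone), glutathione S-transferases (-0.22, 3 fell, or 5), oxidative stress response (-0.20, 0 passed, or 3 fell) and fatty acid and triglyceride synthesis (-0.19, FASN3 at -1.69 and FASN2 at -1.48). With an estimated correlation all 7 list calls in males were lost (adjusted p = 0.587 or more). The male accessory gland list also shifted lower (-0.26, Acp53C14c at -0.98, a call lost without over-expression males replicate 2 or control males replicate 1 or 3 (adjusted p = 0.0583 to 0.231), 4 fell adjusted over the list alone), as did photoreceptor (-0.43, batches -0.93, 0.05 and -0.58), and testis shifted higher (0.25, batches 0.16, 0.23 and 0.30). Left-out arrays ended the glutathione S-transferase call (control males replicate 2, adjusted p = 0.0578), the oxidative stress call (over-expression males replicate 2, 0.0637), the accessory gland call (control males replicate 3, 0.199), the fatty acid synthesis call (over-expression males replicate 1, 0.0555, and control males replicate 2, 0.182, and 3, 0.0692) and the photoreceptor call (over-expression males replicate 1, 0.269, and control males replicate 1, 0.0615, and 3, 0.126).

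Muscle genes shifted higher in over-expression females (median log2 change 0.70, 15 genes, camera adjusted p = 3.0e-09), where 0 passed over all probe sets and 12 rose when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.620), as were all 6 list calls of these females (0.620 or more). For muscle the diet batches gave 0.42, 1.17 and 0.46. The 3 larval serum and fat body proteins had a median of 1.82 (batches 2.55, 2.21 and 0.65), and 77 cuticle proteins had one of 0.14 (batches -0.03, 0.23 and 0.16). Ovary germline genes shifted lower (median -0.65, 15 genes, 4 fell adjusted over the list alone), with batch values of -0.12, -1.47 and -0.11, and the yolk, chorion and vitelline membrane proteins, which camera did not call (median -0.75), gave -0.12, -2.17 and -0.21. In the first principal component of the female arrays over-expression replicate 2 lay farthest out, at -60.5. Neuron genes (median 0.44, batches 0.34, 0.89 and -0.03) and cytochrome P450s (0.10, batches -0.10, 0.36 and -0.02) were called higher as well. Leaving out over-expression females replicate 2 ended the neuron and P450 calls (adjusted p = 0.113 and 0.261), as did leaving out control females replicate 2 (0.0595 and 0.407), and over-expression females replicate 1 ended the neuron call (0.0617).

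**Figure D3:**
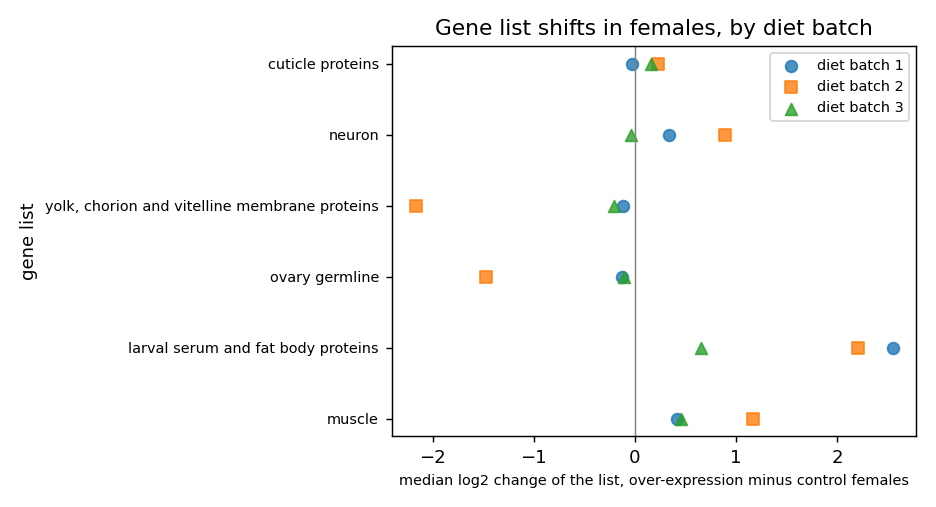
Median log2 change from control to over-expression females (horizontal axis) is plotted for 6 gene lists (vertical axis) within each of 3 diet batches (markers). Batch 2 lies apart for ovary germline (-1.47) and for yolk, chorion and vitelline membrane proteins (-2.17), while muscle is above 0 in each batch (0.42, 1.17 and 0.46).

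In the mean of both sexes the larval serum list (1.49, Fbp1 and Fbp2 of 3 rose), cuticle proteins (0.10, 2 of 77 rose, Edg91 by 0.41 and Cpr49Ac by 0.38, or 3 adjusted over the list alone) and muscle (0.42, 9 rose adjusted over the list alone) were called higher, and ovary germline lower (-0.30). With an estimated correlation all 4 were lost (adjusted p = 0.754 or more). The ovary germline call was lost without over-expression females replicate 2 (adjusted p = 0.0805) or control females replicate 2 (0.0537). Camera called no shift in the other lists in the mean: nuclear receptors (0.02, Hr96 alone of 20 rose), sterol and lipid transport (-0.02), alpha-esterase cluster (0.02), digestive proteases and carbohydrases (-0.03, Jon44E and Jon65Aii rose, Jon74E fell), heat shock proteins (-0.14, Hsc70-2 rose by 0.96), insulin and adipokinetic signalling (-0.0033, Pepck2 rose by 0.65), circadian clock (-0.02), eye pigment and transgene marker (-0.08), RNA interference (-0.28, 1 rose and 3 fell adjusted over the list alone), cytosolic ribosomal proteins (-0.09), immune peptides and effectors (-0.03, Drsl4 alone of 25 fell), testis (0.11), male accessory gland (-0.08, Acp53C14c fell by 0.60), photoreceptor (0.0023), neuron (0.16) and yolk, chorion and vitelline membrane proteins (-0.35). For lipases, sterol and lipid transport, digestive proteases, immune peptides, insulin signalling and photoreceptor the signs of the median, the mean and the test were not all the same. Left-out arrays ended some calls of members: Fbp2 without over-expression females replicate 1 (adjusted p = 0.0533) or control males replicate 3 (0.0608), and Jon65Aii without over-expression males replicate 3 (0.0684) or control males replicate 3 (0.0801). Pepck2 was lost without over-expression females or males replicate 2, or control females or males replicate 2 or 3 (0.0531 to 0.0914). Edg91 held only without over-expression females replicate 3, over-expression males replicate 2, or control females or males replicate 1 (lost at 0.108 to 0.145), and Cpr49Ac only without over-expression females replicate 3 or control males replicate 1 (lost at 0.0598 to 0.156). Acp53C14c held only without over-expression females replicate 2, over-expression males replicate 1 or control males replicate 2 (lost at 0.0606 to 0.156). For Cpr49Ac both control groups, and for Acp53C14c over-expression females, lay below the lower quartile of every array. Hsc70-2 rose by 1.58 in females, with 0.35 in males (limma adjusted p = 0.388).

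Effects that differ between the sexes were tested directly. The effect in arrays labelled knockdown differed in 6 probe sets, among them CG1304 (females minus males, log2 3.45, SE 0.35, limma adjusted p = 1.8e-05), Cht10 (1.33), CG15635 (-1.60) and CG32006 (-1.35). The call of CG32006 held only on leaving out males labelled knockdown replicate 3, and was lost without any of the other 11 arrays (adjusted p = 0.0545 to 0.254). The over-expression effect differed in 31 probe sets, led among named genes by CG11598 (4.08, SE 0.28, adjusted p = 4.1e-08), Ser12 (3.13), CG42828 (2.69), CG31244 (-2.53) and Cyp4d21 (2.43). In 2 of the 6 (CG1304 and Cht10, males) and 6 of the 31 (among them CG11598 and CG42828, females, and Ser12, males) both groups of 1 sex lay below the lower quartile of every array. There a different response cannot be told from a transcript not detected in those groups, and the size is uncertain. CG1304 was detected in males of the other genotypes, at 7.63 with over-expression and 8.05 in the Act5C-GAL4 control. The difference for Hr96 itself was -0.69 (SE 0.44, adjusted p = 0.451). Nonetheless 25 probe sets were called in the same direction in both sexes with over-expression, against 0.875 for independent lists (two-sided Fisher exact p = 3.8e-17 for the 14 higher and 1.5e-13 for the 11 lower), and 1 in opposite directions. Probe sets are not independent, and both sexes share the estimated spread, so these p-values are a guide only. With diet batch as a block 47 were shared in the same direction, and 2 in arrays labelled knockdown, where 0 were shared without it (4 and 5 calls by limma, 795 and 410 at an unadjusted p under 0.05). The count of 31 became 47 with the block, 18 without over-expression females replicate 1, 66 without replicate 3, 16 without over-expression males replicate 1 or 2, 19 without control females replicate 3 and 16 without control males replicate 3.

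Between the manipulations, 5 probe sets were called in both means, all higher in both, against 0.103 for independent lists (two-sided Fisher exact p = 1.6e-08): CG13155, Zip102B, CG18549, 1624393_at and 1630934_at. CG13155 rose by 1.37 in the arrays labelled knockdown and by 1.81 with over-expression, Zip102B by 0.87 and 1.08, and CG18549 by 0.53 and 0.63. Zip102B and 1624393_at were also higher in the Act5C-GAL4 than in the arm-GAL4 control, by 0.66 (limma adjusted p = 0.0094) and 0.65 (0.0071). Between those controls CG13155, CG18549 and 1630934_at were not called. The call of 1630934_at in the means came from males alone, with changes of 4.16 and 4.76, against -0.57 (adjusted p = 0.983) and -0.23 (0.702) in females. None of the 11 limma calls in arrays labelled knockdown moved oppositely among the over-expression calls. Across all probe sets, which are not independent replicates, the changes had a Pearson correlation of -0.09 in the means, -0.32 in females and 0.08 in males. The effects differed from each other in 77 probe sets (27 higher with over-expression, 50 lower), led by Obp57a (over-expression minus labelled knockdown, log2 -2.17, SE 0.31, limma adjusted p = 0.00132), CG11598 (-2.11), Cyp4p2 (1.96), CG12780 (1.90) and Hr96 (1.73). For Cyp4p2 the Act5C-GAL4 control was the genotype that stood apart, at 5.26. Over-expression flies read 7.18 and flies labelled knockdown 7.17. Over-expression males for Obp57a, and all 4 female groups for CG11598, lay below the lower quartile of every array. That count was 151 with diet batch as a block, 40 without females labelled knockdown replicate 1, 41 without arm-GAL4 control males replicate 2, 46 without males labelled knockdown replicate 2, 45 without Act5C-GAL4 control males replicate 3 and 151 without over-expression females replicate 3.

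The control genotypes also differed from each other, although neither carries an Hr96 transgene. CG1304 was higher in Act5C-GAL4 than in arm-GAL4 flies (log2 change 4.13, SE 0.18, limma adjusted p = 1.3e-12, 8.06 against 3.93), as were CG32687 (2.32) and Ser6 (2.02), while Cyp4p2 (-1.95, SE 0.11), Ptp10D (-1.56), the lysozyme gene LysP (-1.40) and Eip63E (-1.35) were lower. These genes were chosen after their values were seen, and CG3699 (1.68) and Sdic3 (-1.36) differed by as much as some of them. CG1304 in the arm-GAL4 control, and Ptp10D in Act5C-GAL4 males, lay below the lower quartile of every array, and the size of these differences is uncertain. In all, limma called 163 probe sets, 80 higher and 83 lower in Act5C-GAL4, and Hr96 differed by -0.01 (SE 0.22). For Cyp4p2 the Act5C-GAL4 control, at 5.26, was the genotype that stood apart: over-expression flies read 7.18 and flies labelled knockdown 7.17.

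Sex gave the scale of a large difference and checked the labels. Yp1, a yolk protein gene, was higher in control females than in males by 8.44 (SE 0.30) on the log2 scale, while Acp26Aa of the accessory gland and Mst84Da of sperm (-7.81, SE 0.14) were lower, and w had no probe set naming it alone. For Acp26Aa both groups of control females lay below the lower quartile of every array, so no size is given. Limma called 11825 probe sets, 8266 higher and 3559 lower in females. Shifting all arrays to a common median gave 12391 higher and 2909 lower and moved the median of all probe sets from 0.20 to 0.40, so the balance of this split is relative to the scaling. Hr96 was higher in females by 1.12 (SE 0.22, limma adjusted p = 1.25e-04).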

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

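Of the tests below, those of the direction and number of shared calls, of over-expression females replicate 2, of the level in the Act5C-GAL4 control and of Hr96 were chosen only after the result was seen, as were the odds ratio of over-expression on chromosome 3 and, in the maturity test, the reassignments and their number, which was lowered from 1000 to 100 after the longer run had been seen. The other chromosome tests, the maturity slope and the regrouping were chosen before.

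Several genes differed between females and males in their response, by a test of the difference itself (females minus males, log2, limma adjusted p under 0.05). For arrays labelled knockdown this held for 6 probe sets: 1630934_at (-4.73), 1640377_s_at (3.62), CG1304 (3.45), CG15635 (-1.60), CG32006 (-1.35) and Cht10 (1.33). In CG1304 the change was 3.18 in females and -0.27 in males, and in 1630934_at it was -0.57 and 4.16. For 1640377_s_at the control genotypes also differed: 5.17 in females and 4.91 in males with arm-GAL4, against 8.76 and 8.69 with Act5C-GAL4. For over-expression 31 probe sets differed, among them CG11598 (4.08), Ser12 (3.13), CG42828 (2.69), CG31244 (-2.53) and Cyp4d21 (2.43). Of these 31, 8 had passed in females alone, 22 in males alone and 1 in both. In 2 of the 6 (CG1304 and Cht10) and 6 of the 31 (CG11598, Ser12 and CG42828 among them) both groups of 1 sex lay below the lower quartile of every array, where a different response cannot be told from a transcript not detected in those groups. CG1304 read 7.63 in over-expression males, 8.05 in Act5C-GAL4 control males and 3.83 in arm-GAL4 control females, so its low values were not those of males as a sex. Camera with its preset correlation called 10 lists as differing between the sexes in arrays labelled knockdown and 11 with over-expression, and 0 with an estimated correlation in either (adjusted p at least 0.426 and 0.515).

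Hr96 was level with its control in the arrays labelled knockdown. A probe set blind to the Hr96 transcript was argued against by the over-expression arrays, where the lower 95% bound of the log2 change was 1.29. A whole-body fall by 1 or more on the log2 scale was argued against by the lower bound of -0.45 in the mean of both sexes, which is 73.5% of control. A hairpin transcript read by the same probe set could hide a fall, and the measured change of 0.012 leaves this open because probe and hairpin sequences are not at hand. A fall in protein or in single tissues, the biological alternative, was not tested by whole-body RNA.

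The over-expression calls were set against properties of single arrays and of the control. Younger flies could contribute, which stays open: 66.5% of 349 called probe sets had the sign of the within-group slope on an index of 80 larval serum and cuticle genes, against 63.0% of all probe sets, and the 66.5% lies between the bounds set beforehand and was reached by 41 of 1000 reassignments of the index within groups, or 5 of 100 in the shorter run. Without over-expression females replicate 2, 229 of the 353 calls stayed, just short of the bound for excluding that array as the main source, so it stays open. A level peculiar to the Act5C-GAL4 control was argued against as the whole cause, since 15.3% (54) of the calls had a mean in the remaining genotypes nearer to the over-expression arrays, but it stays open for those 54, Cyp4p2 among them. A response to the receptor, the biological alternative, cannot be told apart from what is left open.

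The calls shared by the manipulations were all higher in both means, 1630934_at through males alone (4.16 labelled knockdown and 4.76 with over-expression, against -0.57 and -0.23 in females). Of these 5, 0 moved in opposite directions. Because Hr96 had not fallen in the arrays labelled knockdown, no opposite dose was there to read, and a response to receptor dose stays open. For the same reason the direction of these 5 calls cannot argue for or against an opposite response. Sequence or background shared by both transgene lines and absent from both controls could give such sharing, and the 5 shared calls leave it open, because each Hr96 transgene was tested in 1 line. Background carried with the transgene chromosome stays open: for chromosome 3 and the arrays labelled knockdown the odds ratio was 0.206 (95% interval 0.0045 to 1.70, exact p = 0.139, 1 of 7 genes), and for chromosome 2 and over-expression it was 1.07 (0.840 to 1.36, exact p = 0.590, 122 of 301 genes). On chromosome 3 the over-expression calls had an odds ratio of 1.30 (1.03 to 1.65, exact p = 0.0256, 154 of 301 genes).

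Over 100 splits of the arrays with the sexes kept apart, 1, the real one, gave as many calls in each mean, which excludes a chance split that ignores the diet batches. Among the 17 splits that part as many same-batch pairs the real one alone gave as many, but 17 are too few for a share under 0.05. The arrays labelled knockdown gave 11 against at most 6 in another split, also among those 17, and over-expression 353 against 140, or 44 among those 17. Within a sex the 10 splits are too few for a share under 0.05. The real values and the highest others, with 1 split as large in each, were 4 and 1 in females labelled knockdown, 5 and 0 in males, 164 and 1 in over-expression females, and 219 and 61 in males.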

How the results depend on the processing

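None of these alternatives was chosen after the data were seen, and the cause of a change was not tested unless stated. Hr96 is not among the named genes counted here and is given apart. Of 1060 values of the other named genes under other settings, 976 kept direction and side of the threshold, 84 kept direction but missed the threshold, and 0 reversed. Of the 84, 53 came from fits on only the compared arrays, where 66 of 119 were kept. On leaving out 1 array, 966 of 1158 were kept and 192 missed it. With the diet batch as a replicate block the calls numbered 7 and 8 in females and males labelled knockdown, 383, 358 and 595 in over-expression females, males and the mean, 47 for the sex difference of over-expression and 151 for over-expression minus labelled knockdown; calls shared by the sexes became 2 and 47, no other count moved by over 1.5 times (16 in the mean labelled knockdown, 7 for its sex difference, 243 between controls and 12227 between sexes), and the calls of all 119 values of named genes were kept. Of the 35 list calls the block ended those of glutathione S-transferases (adjusted p = 0.0746) and cuticle proteins (0.0537) in females labelled knockdown, kept the other 33 and gave 40 in all. With array weights the counts were 13, 12 and 36 for the arrays labelled knockdown, 664 and 686 in over-expression males and the mean, 82 for the sex difference, 260 between manipulations and 254 between controls. With 1 probe set per gene, where fewer features are tested, they were 2, 3 and 7 for the arrays labelled knockdown, 3 for their sex difference, 3 shared between manipulations and 0 opposite between the sexes with over-expression. With only the compared arrays, where fewer samples set the spread, they were 1 in females labelled knockdown, 12, 101 and 191 with over-expression, 14 for the sex difference and 102 between controls, and Hr96 missed the threshold at 1.40 in females (adjusted p = 0.114) and 2.09 in males (0.0910). A 2-fold minimum left 5 in the mean labelled knockdown, 75, 93 and 83 with over-expression, 35 between manipulations, 25 between controls and 4754 between sexes. Trend and robust settings gave 1 call shared by the sexes labelled knockdown. The 35 list shifts became 0 with an estimated correlation and 0 with fry. Hr96 in the mean labelled knockdown, not called in any setting, turned to -0.0034 with joint quantile normalization and -0.012 with array weights.

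Leaving out 1 array gave ranges of 4 to 8 and 5 to 8 in females and males labelled knockdown, 36 to 723, 90 to 193 and 212 to 565 in over-expression females, males and the mean, 16 to 66 for the sex difference and 40 to 151 between manipulations. Hr96 ranged from 1.24 to 1.65 in over-expression females and from -0.061 to 0.077 in the mean labelled knockdown. The cuticle list in males labelled knockdown ranged from -0.021 to 0.14 and the accessory gland list in the mean from -0.021 to 0.22. Signal near background limits what dim probe sets can show.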

Other observations

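The list tests between control genotypes and between sexes were chosen only after the result was seen.

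Control females and males differed in 7 lists by camera with its preset correlation. Yolk, chorion and vitelline membrane proteins were higher in females in 17 of 17 genes (median log2 difference 5.63, adjusted p = 0.84 with an estimated correlation), as were 14 of 15 ovary germline genes (4.42, adjusted p = 0.49 with an estimated correlation) and 13 of 14 genes of fatty acid oxidation (0.62, adjusted p = 0.49 likewise). Testis genes were lower in 24 of 26 (-5.97), the call that held with an estimated correlation (adjusted p = 0.030), and accessory gland genes in 18 of 18 (-7.33, adjusted p = 0.089 with an estimated correlation). Of 25 lipases 1 was higher and 10 were lower in females, with a median of 0.0019 and a mean of -1.27 (adjusted p = 0.49 with an estimated correlation). Of 41 cytosolic ribosomal proteins 34 were higher and 7 lower (median 0.68, adjusted p = 0.94 with an estimated correlation).

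Between the control genotypes, muscle genes were higher in Act5C-GAL4 than in arm-GAL4 flies (median 0.41, 15 genes, adjusted p = 0.85 with an estimated correlation), and fatty acid oxidation genes were higher (0.14, 2 of 14 rose, adjusted p = 0.33 with an estimated correlation), while testis genes were lower (-0.12, adjusted p = 0.85 with an estimated correlation). Of the 163 calls between the controls 34 were also called with over-expression, 26 of them in the opposite direction, against 3.07 for independent lists. In 100 simulations without effects the number was 0, which sets no bound for data with effects, and the value for independent lists leaves the shared arrays out of account. These comparisons share the Act5C-GAL4 arrays, 3 in each sex, too few to split, so part of the sharing may come from the shared controls; this is the control level tested among the over-expression calls (15.3%). Eip63E, for example, read 8.22 with over-expression, 6.85 in its control and 8.15 and 8.20 in the remaining genotypes, Jon44E read 10.2, 8.71, 9.85 and 10.1, and CG12780 read 8.38, 6.66, 7.46 and 7.63.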
